A study of Mus musculus with 12 samples.

How the data were processed

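Total RNA from whole liver was isolated with Trizol and an RNeasy column with DNase treatment, labelled with biotin as cRNA and hybridized to 1-colour Illumina bead arrays for mouse, per the labels' protocols. The 12 arrays fall into 4 groups of 3 by sex and vector (female eGFP, female hUSF1, male eGFP and male hUSF1), per the labels. The mice were C57BL/6J and 4 months old, and livers were taken 5 days after injection, per the labels. The labels give no batch, slide or day.

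The values used are the processed signal intensities that the authors deposited, 1 column per array, on a linear scale. In each array the lowest deposited intensity was 25.2, the median 34.2, the upper quartile 58.6 and the highest 7670. The sorted values of the 12 columns agree within 0.0727%, which is how quantile normalization leaves columns, but no source used here states the method, and the software is not given in the sources used here. Whether background had been subtracted is unknown. A second deposited table of intensities that had not been normalized has 12 columns whose names match no label, so all 12 are unmapped and that table is not analysed here. Arrays give no counts, and their number and the signal over background limit the precision.

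The plan fixed before the data were examined, namely the samples, models, alternatives, gene lists and the rule for naming genes, assumed the table that had not been normalized. Use of the authors' normalized table is a departure from it, with the planned settings for a table without detection p-values. Intensities were corrected with normexp on all probes with an offset of 50, quantile normalized (which moved almost nothing) and taken to log2, with limma 3.58.1 in R 4.3.3. The offset makes the fold changes of dim genes smaller than the ratios of their intensities. Probes were kept if they were above their array's median in at least 3 of 12 arrays, which left 25780 of 45281. Where a gene had several kept probes, as 5378 named genes had, the probe with the highest mean log2 signal stood for it, and kept probes with no symbol stood for themselves. This gave 17496 features.

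Gene symbols came from the platform's annotation, in which 34885 probes have 1 symbol, 18 have several and 10378 have none. Of the probes with 1 symbol 34807 were matched by Entrez identifier to a mouse gene table of the assembly GRCm38.p6, used for names only, which changed 0 symbols. No coordinates are given because the probes were not aligned.

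A limma model with 4 group means was fitted to all 12 arrays, with moderated statistics (eBayes). Contrasts were hUSF1 minus eGFP in females, in males and averaged over both sexes, the female minus the male effect (the interaction), and female minus male under each vector. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 17496 features of each contrast, with a threshold of 0.05. An adjusted p beside a single gene is from this test. A fold against a group whose arrays all lie at or below their median intensity was computed against that median and is given as a lower bound.

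The 39 gene lists cover pathways, cell types and sex-biased genes. They hold 1165 entries, of which 1164 were matched and 904 distinct genes were measured. Each was tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, with adjustment over the 39 lists of a contrast. An adjusted p beside a list is from this test. The alternatives were camera with a correlation estimated per list and fry, which asks whether the members move one way on balance and does not compare them with other genes. Beside the count over all genes the text gives the count with p adjusted over the list alone.

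Genes were named by rule. For each hUSF1 comparison these are Usf1, Usf2 and the 10 largest rises and 10 largest falls among named genes that passed and whose hUSF1 arrays all lay on 1 side of the eGFP mean of their sex. For each list they are up to 4 members with the smallest p in the averaged comparison, or in the sex difference for the sex-biased and sex chromosome lists. For the interaction they are the 10 with the smallest p, and for the sex difference in eGFP livers the 10 largest in each direction. Not all of them are printed. Scd1 in the interaction was chosen after its values were seen, because of its place in the female comparison.

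The method was tested on simulated data made with the spread of the real arrays, with 17483 features. The genes changed were drawn from named genes in no list with a mean intensity over 100, so recovery of dimmer genes was not tested. Of 99 genes changed by 0.5 log2 units the test recovered 80.8% in the averaged comparison, 57.6% in females and 65.7% in males. Of 93 genes changed by 1 unit it recovered 97.8%, 92.5% and 92.5%, with 0 in the wrong direction. Of the calls made in the averaged, female and male comparisons 7.35%, 5.95% and 5.65% were unchanged genes. A list shifted by 0.5 units was recovered in the averaged comparison, and 0 of 38 other lists were called. The noise of each simulated probe was drawn independently, so members of a list were not correlated. The simulation therefore does not show how often camera calls an unchanged list on real arrays.

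Alternatives tried were the deposited values without background correction, cyclic loess, no filter, a filter on all 12 arrays, all kept probes, the compared arrays alone, eBayes with trend and robust options, array weights, a replicate block and leaving out each array. An offset of 16 was added after the data had been seen. Other splits of the arrays into groups of the same sizes were fitted with the same model. For the averaged effect and the interaction they were fitted again after the estimate of the other effect had been taken out of every feature. This was added after the data had been seen.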

Results

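Gene expression was measured in whole mouse liver 5 days after an adenovirus was given through the tail vein. The virus carried either the cDNA of human USF1 (hUSF1), a transcription factor that binds E-box motifs, or enhanced green fluorescent protein (eGFP) as the control. Every group received a virus, so rises and falls with hUSF1 are relative to eGFP livers. An effect of hUSF1 cannot be told apart from an opposite effect of eGFP. Female and male C57BL/6J mice were used, which gave 4 groups of 3 arrays each and 12 arrays in all. The labels do not say whether the 3 samples of a group are separate animals, so p-values measure the spread between these samples. Each array held 45281 probes, and 17496 features were tested, of which 12997 are named genes and 4499 are probes with no gene symbol. The number of arrays limits the precision of every value. The title of the series names the question: which genes differ in expression in association with USF1.

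The first principal component of the normalized log2 signal held 47.6% of the variance and separated the sexes, with the 6 female arrays between -22.6 and -4.54 and the 6 male arrays between 3.09 and 24.1. It also separated the vectors within each sex. Female eGFP arrays lay between -22.6 and -16.9 and female hUSF1 arrays between -9.75 and -4.54. Male eGFP arrays lay between 3.09 and 11.5 and male hUSF1 arrays between 14.9 and 24.1. The second held 18.6% and separated the vectors, with the hUSF1 arrays between -11.4 and -4.58 and the eGFP arrays between 0.107 and 17.6. Correlations between arrays of the same group ran from 0.993 to 0.996, and those between groups from 0.967 to 0.992.

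**Figure D1:**
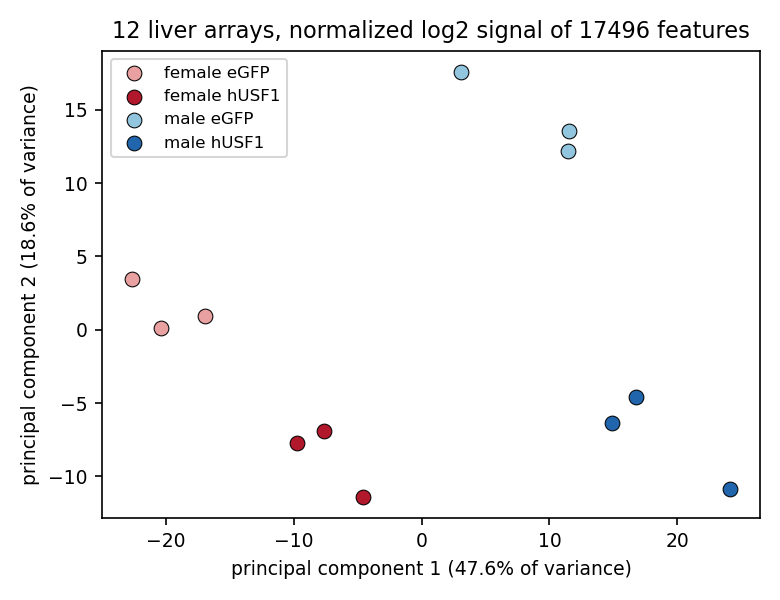
The 12 arrays on the first 2 principal components of the normalized log2 signal of 17496 features, 1 point per array, coloured by sex and vector. Female arrays lie below 0 and male arrays above 0 on component 1, and hUSF1 arrays lie below eGFP arrays on component 2. Within each sex hUSF1 arrays lie above eGFP arrays on component 1.

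The first comparison set hUSF1 against eGFP livers, averaged over both sexes with 6 arrays on each side. In hUSF1 livers 21 of 24 antigen presentation genes and 21 of 30 T and NK cell markers fell, and 18 of 41 cytochrome P450 and drug metabolism genes and 9 of 15 genes of the growth hormone axis rose. The largest fall was that of Ubd, which encodes a ubiquitin-like protein induced by inflammatory cytokines. Its deposited intensity was 1474 ± 206 (SD, n = 3) in female eGFP and 486 ± 25.9 in female hUSF1 livers, and 1585 ± 327 in male eGFP and 267 ± 114 in male hUSF1 livers, a change of -2.05 log2 units (SE 0.18, adjusted p = 0.000269). H2-Ab1, a chain of the major histocompatibility complex class II, stood at 1876 ± 98.6 and 926 ± 116 in females and at 1809 ± 57.7 and 627 ± 154 in males, and fell by 1.26 (SE 0.10, adjusted p = 0.000174). In limma's test 2626 features passed an adjusted p of 0.05, 1303 higher and 1323 lower with hUSF1, and 17 of them changed by more than 1 log2 unit. At an unadjusted p under 0.05 the count was 4937.

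Of the 24 measured genes of antigen processing and presentation 21 fell and 0 rose, and 21 fell when p was adjusted over the list alone (median change -0.41 log2, camera adjusted p = 3.0e-18 and adjusted p = 0.0175 with an estimated correlation). The class II genes H2-Eb1, H2-DMa and H2-DMb1 fell by 1.26, 1.07 and 1.02, and Cd74, the invariant chain that escorts class II molecules, fell by 1.26 (SE 0.13, adjusted p = 0.000394). Each of these genes was below the eGFP mean of its sex in all 6 hUSF1 arrays, which the naming rule for the largest falls required. Of 30 T and NK cell markers 21 fell and 0 rose, 23 when adjusted over the list alone (median -0.15, adjusted p = 2.8e-15, adjusted p = 0.0175 with an estimated correlation). Among them were Thy1 (-1.01), a surface protein of T cells, Cd3g (-0.74), a chain of the T cell receptor complex, the chemokine gene Ccl5 (-0.60) and Nkg7 (-0.61), a gene of cytotoxic granules. Of 40 interferon response genes 23 fell and 0 rose, 28 when adjusted over the list alone (median -0.32, adjusted p = 6.2e-15), although this call was lost at adjusted p = 0.0925 with an estimated correlation. The guanylate-binding protein genes Gbp2 and Gbp3 fell by 0.94 and 0.67, the chemokine gene Cxcl9 by 0.92 and the antiviral synthetase gene Oas1g by 0.72, with other probes of Oas1g at -0.53 and -0.09. Of 30 macrophage and Kupffer cell markers 17 fell and 1 rose, 19 and 1 when adjusted over the list alone (median -0.26, adjusted p = 3.3e-09, adjusted p = 0.125 with an estimated correlation), including the chemokine genes Ccl3 (-0.64) and Ccl4 (-0.92, its other probe -0.32) and the pore-forming protein gene Mpeg1 (-0.73). Another probe of Mpeg1 read -0.09.

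Of 28 proteasome genes 14 fell and 0 rose, 21 when adjusted over the list alone (median -0.19, adjusted p = 3.5e-11, adjusted p = 0.0175 with an estimated correlation). Psmb5, a catalytic subunit of the core particle, fell by 0.43 (SE 0.03, adjusted p = 0.000155), and Psmc3 and Psmc5, ATPases of the regulatory particle, fell by 0.38 and 0.31, although a second probe of Psmc5 read -0.03. Ly6d, a surface protein gene, fell by 1.67 (SE 0.23), and its second probe read -1.48. Srxn1, which encodes an enzyme that repairs oxidized peroxiredoxins, fell by 1.12 (SE 0.19). Tubb2b, a tubulin gene, fell by 1.02 on the probe used, while its other 4 probes read between -0.48 and -0.01.

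The genes that rose most included Hamp2, a relative of the iron hormone hepcidin (1.32, SE 0.20, adjusted p = 0.00208), the carboxylesterase gene Ces3b (1.23, its other probes 0.84 and 0.16), Rgs16, a regulator of G protein signalling (1.12), Igfbp2, a binding protein of insulin-like growth factors (1.09), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.05, SE 0.21, adjusted p = 0.00853). Cyp7a1 intensity was 965 ± 323 (SD, n = 3) in female eGFP and 1763 ± 404 in female hUSF1 livers, and 688 ± 143 and 1666 ± 614 in males. Sult2a8 rose by 0.97, Nrep by 0.97 (SE 0.12), the kinase gene Dclk3 by 0.90 and Socs2, a feedback inhibitor of growth hormone signalling, by 0.82. All of these were above the eGFP mean of their sex in 6 of 6 hUSF1 arrays, which the naming rule required. Hsd3b5, a steroid dehydrogenase gene of male liver, passed with all arrays (0.81, adjusted p = 0.0475), but leaving out any of 10 arrays ended the call (adjusted p between 0.0747 and 0.0926), the exceptions being male eGFP replicate 1 and male hUSF1 replicate 3. Its intensity in females was 31.97 ± 2.71 with eGFP and 36.19 ± 2.36 with hUSF1, close to the arrays' median of 34.2, and the change there was 0.11 (adjusted p = 0.916).

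Of 15 genes of the growth hormone and insulin-like growth factor axis 9 rose and 1 fell, with the same counts when adjusted over the list alone (median 0.31, adjusted p = 2.7e-05, adjusted p = 0.0175 with an estimated correlation). Ghr, the growth hormone receptor gene, rose by 0.45, and Igfals, a carrier subunit of circulating insulin-like growth factors, by 0.60. Of 41 cytochrome P450 and drug metabolism genes 18 rose and 0 fell, 21 and 2 when adjusted over the list alone (median 0.18, adjusted p = 1.0e-08, adjusted p = 0.0278 with an estimated correlation). Examples were Aox3, an aldehyde oxidase gene (0.76, SE 0.09), Cyp3a13 (0.35) and Cyp2e1 (0.28, SE 0.03). Of 33 amino acid and urea metabolism genes 13 rose and 0 fell, 21 and 2 when adjusted over the list alone (median 0.27, adjusted p = 7.9e-09, adjusted p = 0.112 with an estimated correlation). They included Hal (0.69, its other probe 0.24) of histidine breakdown, Hpd (0.63) and Hgd (0.31) of tyrosine breakdown, and Otc (0.38) of the urea cycle. Of 25 hepatocyte markers 8 rose and 0 fell, 9 when adjusted over the list alone (median 0.15, adjusted p = 3.8e-05, adjusted p = 0.141 with an estimated correlation). The falls of the T and NK cell and macrophage markers given above were measured in the same comparison as these rises.

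Of 19 bile acid genes 6 rose and 1 fell, 9 and 1 when adjusted over the list alone (median 0.11, adjusted p = 0.000475, adjusted p = 0.0576 with an estimated correlation). Besides Cyp7a1 these were led by Abcb11, the bile salt export pump (0.49), Nr1h4, the bile acid receptor FXR (0.39), Cyp27a1 (0.33, its other probes 0.28 and 0.08) and Slc27a5 (0.54). Of 18 cholesterol synthesis and uptake genes 6 rose and 0 fell, 10 when adjusted over the list alone (median 0.16, adjusted p = 0.000212, adjusted p = 0.267 with an estimated correlation), among them Insig1 (0.52) and Ebp (0.33). A further probe of Insig1 read -0.06. Of 28 fatty acid and triglyceride synthesis genes 7 rose and 1 fell, 9 and 2 when adjusted over the list alone (median 0.09, adjusted p = 0.0126, adjusted p = 0.178 with an estimated correlation). Acss2, which makes acetyl-CoA from acetate, rose by 0.57 on the probe used and by 0.05 on another. Acly, which makes it from citrate, rose by 0.42. Slc25a1, the mitochondrial citrate carrier, rose by 0.28. The gene that fell was Cidec (-0.85, SE 0.11), whose protein coats lipid droplets. Khk, the fructokinase gene, rose by 0.48 (SE 0.05, adjusted p = 0.000333), and Insr, the insulin receptor gene, by 0.48 on the probe used and by 0.03 on another. Their list of 27 glucose metabolism genes had 5 that rose and 1 that fell, 9 and 3 when adjusted over the list alone (median 0.04, adjusted p = 0.0421, adjusted p = 0.302 with an estimated correlation).

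Of 27 oxidative stress and NRF2 target genes 11 fell and 0 rose, 14 and 1 when adjusted over the list alone (median -0.16, adjusted p = 1.0e-05, adjusted p = 0.232 with an estimated correlation), among them Srxn1, Gclc (-0.55), the catalytic subunit of glutathione synthesis, and Txnrd1 (-0.31), a thioredoxin reductase gene. In males alone 9 of these genes fell (median -0.29). In females 0 fell and 2 rose, 5 and 3 when adjusted over the list alone (median -0.07, adjusted p = 0.298). Of 16 heat shock protein genes 9 fell and 0 rose, 10 when adjusted over the list alone (median -0.21, adjusted p = 7.2e-05, adjusted p = 0.065 with an estimated correlation), including Hspb8 (-0.35). Of 40 cell cycle genes 9 fell and 0 rose, 10 when adjusted over the list alone (median -0.15, adjusted p = 6.0e-06, adjusted p = 0.284 with an estimated correlation). These included Ccne1 (-0.29), the cyclin E1 gene, Rrm2 (-0.51), a subunit of ribonucleotide reductase, and Mcm6 (-0.28), part of the replicative helicase. One other probe of each of the last 2 genes read -0.02. Of 29 genes of the unfolded protein and integrated stress response 5 fell and 2 rose, 9 and 2 when adjusted over the list alone (median -0.09, adjusted p = 0.019, adjusted p = 0.112 with an estimated correlation), with Creld2 at -0.52 and Fgf21, a liver hormone, at -0.54.

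Of 33 complement and coagulation genes 10 rose and 0 fell, 12 when adjusted over the list alone (adjusted p = 8.3e-05, adjusted p = 0.259 with an estimated correlation), with Klkb1, the prekallikrein gene, at 0.56 and F9, coagulation factor IX, at 0.27. Of 35 male-biased liver genes 10 rose and 0 fell, 12 when adjusted over the list alone (adjusted p = 0.000122, adjusted p = 0.232 with an estimated correlation). The median changes of the oxidative phosphorylation, cytosolic ribosomal protein and housekeeping lists were 0.05, -0.08 and -0.10, with adjusted p = 0.0062, 0.00343 and 0.00853 that became adjusted p = 0.259, 0.232 and 0.109 with an estimated correlation. Extracellular matrix genes and neutrophil markers had medians of -0.09 and -0.08 (adjusted p = 0.0198 and 0.0407, adjusted p = 0.485 and 0.371 with an estimated correlation). Cyclic loess ended the calls for glucose metabolism and for neutrophil markers (adjusted p = 0.0511 for both), and with fry the neutrophil and extracellular matrix lists did not pass (adjusted p = 0.0816 and 0.153). Some of the averaged calls came with a call in 1 sex only at the preset correlation. The lists of amino acid and urea metabolism, cholesterol synthesis, hepatocyte markers, complement, the cell cycle, glucose metabolism, fatty acid synthesis, oxidative phosphorylation, male-biased genes and housekeeping genes passed in females and not in males (adjusted p = 0.114, 0.353, 0.0718, 0.222, 0.114, 0.695, 0.174, 0.221, 0.0718 and 0.114 in males). The NRF2, ribosomal protein and extracellular matrix lists passed in males and not in females (0.298, 0.251 and 0.278 in females). With an estimated correlation 0 of these calls within a sex held. A call in 1 sex only does not show a difference between the sexes. At the preset correlation the interaction did not pass for hepatocyte markers, glucose metabolism, fatty acid synthesis or oxidative phosphorylation. Nor did it pass for male-biased, housekeeping, ribosomal protein or extracellular matrix genes. For the other lists just named it passed at the preset correlation only. Leaving out 1 array could also end list calls within a sex. In females this held for fatty acid synthesis, the circadian clock, oxidative phosphorylation and housekeeping genes (highest adjusted p = 0.1655, 0.0723, 0.108 and 0.0723). In males it held for bile acid, P450, ribosomal protein and extracellular matrix genes (highest adjusted p = 0.0557, 0.1435, 0.0894 and 0.25). For the averaged effect leaving out 1 array ended 3 list calls. The neutrophil call ended without female eGFP replicate 2 (adjusted p = 0.135), female hUSF1 replicate 2 (0.0515), male eGFP replicate 3 (0.0924), male hUSF1 replicate 1 (0.0713) or male hUSF1 replicate 3 (0.0642). The extracellular matrix call ended without female eGFP replicate 2 (0.0834), female hUSF1 replicate 1 (0.0529), male eGFP replicate 2 (0.0843) or male hUSF1 replicate 1 (0.0794). The call for glucose metabolism ended without female eGFP replicate 1 (0.154), female eGFP replicate 2 (0.0576), female hUSF1 replicate 3 (0.0948), male eGFP replicate 2 (0.0519), male eGFP replicate 3 (0.0572) or male hUSF1 replicate 1 (0.0713).

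The lists that did not pass with camera included those closest to USF1 itself. Of 16 reported USF1 target genes 3 rose and 1 fell, 4 and 1 when adjusted over the list alone (median 0.05, adjusted p = 0.328). With fry, which does not compare a list with other genes, this list passed upwards (adjusted p = 0.0220), as did the erythroid list downwards (0.0470). Pklr, the liver pyruvate kinase gene, rose by 0.30 (SE 0.06, adjusted p = 0.00563), Agt, angiotensinogen, by 0.33 (adjusted p = 0.0394) and Apoe, apolipoprotein E, by 0.21 (adjusted p = 0.0335), while Hmox1, heme oxygenase 1, fell by 0.44 (adjusted p = 0.0258). Each was on 1 side of the eGFP means in 6 of 6 hUSF1 arrays. Leaving out 1 of 8 arrays ended the call of Agt (adjusted p between 0.0522 and 0.0919, the exceptions being female eGFP 3, female hUSF1 3, male eGFP 3 and male hUSF1 2) and that of Apoe (between 0.0503 and 0.0785, the exceptions being female eGFP 3, female hUSF1 3, male eGFP 1 and male hUSF1 2). That of Hmox1 ended without female eGFP replicate 3 (0.052), female hUSF1 replicate 2 (0.0607) or male hUSF1 replicate 1 (0.0609). A replicate block also ended the call of Apoe (adjusted p = 0.058), and fitting without a filter that of Agt (adjusted p = 0.0631). Of 16 USF and E-box factors 1 rose (adjusted p = 0.619), and 2 rose and 1 fell when adjusted over the list alone. Mouse Usf1 read 0.02 (SE 0.05, adjusted p = 0.816) and was higher in 3 of 6 hUSF1 arrays. On the probe used Usf2 read 0.17 (SE 0.05, adjusted p = 0.051), higher in 5 of 6. Another kept probe of Usf2 had mean intensities of 44.73 with eGFP and 52.43 with hUSF1 in females. In males it went the other way, with 66.35 and 56.29. These probes were made for the mouse genes and whether they bind the human transcript is unknown, so the arrays do not check which vector a liver received.

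The remaining lists did not pass with camera either. Of 26 lipoprotein and lipid transport genes 4 rose and 2 fell, 6 and 2 when adjusted over the list alone (adjusted p = 0.328), with Abcg8, a sterol exporter, at 0.48 and Lpl, lipoprotein lipase, at -0.52. Of 30 fatty acid oxidation and PPARα target genes 6 fell and 1 rose, 7 and 1 when adjusted over the list alone (adjusted p = 0.0776), with Plin2, a lipid droplet protein gene, at -0.56. Of 34 endothelial and stellate cell markers 3 rose and 3 fell, the same numbers as when adjusted over the list alone (adjusted p = 0.732), among them Reln at 0.44, with its other probe at 0.05, and Stab2, a scavenger receptor of sinusoidal endothelium, at 0.29. Cdh5, the cadherin gene of endothelium, fell by 0.21 (SE 0.05, adjusted p = 0.0209) in 6 of 6 hUSF1 arrays. Its other probe read -0.215. The call ended without female hUSF1 replicate 2 (adjusted p = 0.0525). Among 10 B and plasma cell markers and among 9 cholangiocyte markers 0 genes passed, over all genes or adjusted over the list alone (adjusted p = 0.734 and 0.732). The acute phase list of 28 genes had 1 that rose and 1 that fell, and 0 when adjusted over the list alone (adjusted p = 0.912), with a median of 0.01, a mean of -0.04 and a test statistic on the upper side. The median of the B and plasma cell list lay above 0 and its mean and test below 0. The circadian clock (adjusted p = 0.173), iron and heme (0.411), p53 (0.376), erythroid (0.103), lysosome (0.856), female-biased (0.0536) and sex chromosome (0.411) lists also missed the threshold.

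**Figure D2:**
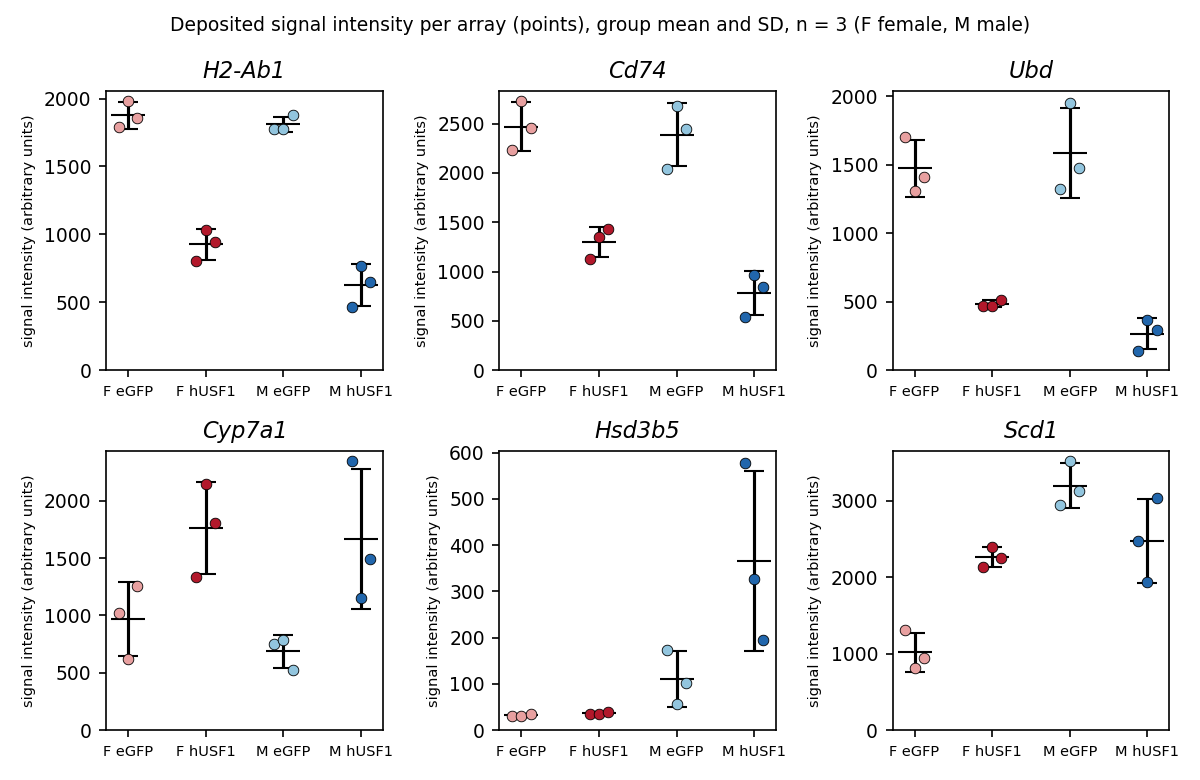
Deposited signal intensity (arbitrary units) of 6 genes in each of the 12 arrays (points), with the group mean and SD (n = 3). H2-Ab1, Cd74 and Ubd lie lower in every hUSF1 array than in any eGFP array of the same sex, Cyp7a1 means are higher with hUSF1 in both sexes, and Scd1 rises in females from 1019 to 2263.

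Within females, hUSF1 livers had 14 of 41 cytochrome P450 and drug metabolism genes and 6 of 15 growth hormone axis genes that rose, and 11 of 30 T and NK cell markers that fell. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose from an intensity of 1019 ± 257 (SD, n = 3) to 2263 ± 128, by 1.16 log2 units (SE 0.17, adjusted p = 0.00508). Ces3b rose by 1.39 (SE 0.26, adjusted p = 0.0104), the P450 gene Cyp2c50 by 1.06, although its other probes read 0.18 and 0.15 in the averaged comparison, Rgs16 by 1.05, Hal by 1.02 and Cib3, a calcium-binding protein gene, by 1.07. Ugt1a5, a glucuronosyltransferase gene, rose by 0.99 (SE 0.13, adjusted p = 0.00332). Ubd fell by 1.55 (SE 0.26), and so did the actin-binding peptide gene Tmsb10 (-1.17, SE 0.15, adjusted p = 0.00304), the interferon-induced chemokine gene Cxcl10 (-1.11), Thy1 (-1.02), Fbp2, a fructose bisphosphatase of muscle (-1.02), Tnfrsf12a, the receptor of the cytokine TWEAK (-1.01), H2-Ab1 (-1.01) and H2-Eb1 (-0.93). In the averaged comparison, where Tmsb10 and Cxcl10 read -0.91 and -0.89, other probes of Tmsb10 read -0.13 and -0.85 and that of Cxcl10 -0.25. All of the genes named were on 1 side of the eGFP mean in 3 of 3 hUSF1 arrays, which the naming rule required.

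In females 1373 features passed, 618 higher and 755 lower, 24 of them by more than 1 log2 unit, and 3861 had an unadjusted p under 0.05. Of the 39 gene lists 21 passed, 13 up and 8 down, and 3 held with an estimated correlation. In the P450 list 14 of 41 genes rose and 0 fell, 26 when adjusted over the list alone (median 0.32, adjusted p = 0.0333 with an estimated correlation). In the growth hormone list 6 of 15 rose, 8 and 1 fallen when adjusted over the list alone (median 0.23, adjusted p = 0.0372 with an estimated correlation), and in the T and NK cell list 11 of 30 fell, 20 when adjusted over the list alone (median -0.21, adjusted p = 0.0372 with an estimated correlation). Amino acid and urea genes had the smallest camera p, with 16 of 33 risen and 19 when adjusted over the list alone, against 1 fallen (median 0.39, adjusted p = 2.1e-13, adjusted p = 0.0784 with an estimated correlation). Hamp2 (1.25), Sult2a8 (1.24), Igfbp2 (1.09), Ly6d (-1.59) and Slc4a1 (-1.28) also passed, and all 5 calls ended without female hUSF1 replicate 2 (adjusted p = 0.0882, 0.112, 0.086, 0.0594 and 0.0628) and without female eGFP replicate 2 (0.0822, 0.113, 0.112, 0.0599 and 0.0538). Female eGFP replicate 3 ended those of Hamp2 (0.0502), Sult2a8 (0.0907) and Slc4a1 (0.0543) when left out, female hUSF1 replicate 1 those of Hamp2 (0.0663), Sult2a8 (0.074) and Igfbp2 (0.0861), and female eGFP replicate 1, female hUSF1 replicate 3 or male hUSF1 replicate 3 that of Igfbp2 (0.11, 0.107 and 0.0542). The count of 1373 became 556 without female eGFP replicate 2, 865 without female eGFP replicate 3, 577 without female hUSF1 replicate 2 and 777 without female hUSF1 replicate 3.

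Within males, Ubd and several class II and interferon-induced genes fell with hUSF1. Ubd fell by 2.54 log2 units (SE 0.26, adjusted p = 0.00042), and Cd74 fell from an intensity of 2388 ± 323 (SD, n = 3) to 783 ± 224 (-1.61, SE 0.19, adjusted p = 0.000967). H2-Eb1, H2-Ab1 and H2-DMa fell by 1.59, 1.52 and 1.31. Falls were also seen in the interferon-induced genes Cxcl9 (-1.28) and Gbp7 (-1.25), in Ly6d (-1.76) and in Srxn1 (-1.43, SE 0.27, adjusted p = 0.00792). Krt18, a keratin gene of epithelial cells including hepatocytes, fell by 1.40 (SE 0.15, adjusted p = 0.000538). Hamp2 rose by 1.39 (SE 0.28, adjusted p = 0.00962), Rgs16 by 1.19, Gm4956 by 1.13, Nrep and Dclk3 by 1.00 each and Aox3 by 0.92 (SE 0.12, adjusted p = 0.00175). Each was on 1 side of the eGFP mean in 3 of 3 hUSF1 arrays, which the naming rule required.

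In males 2403 features passed, 1226 higher and 1177 lower, 43 of them by more than 1 log2 unit, and 4927 had an unadjusted p under 0.05. Of the 39 gene lists 13 passed, 3 up and 10 down, and 0 held with an estimated correlation, where 15 passed with fry. The antigen presentation list had 17 of 24 genes fallen and 19 when adjusted over the list alone (median -0.63, adjusted p = 4.2e-17, adjusted p = 0.0563 with an estimated correlation). The interferon list had 18 of 40 fallen and 27 when adjusted over the list alone (median -0.35, adjusted p = 6.1e-15, adjusted p = 0.144 with an estimated correlation), and the NRF2 list 9 of 27 fallen and 15 when adjusted over the list alone (median -0.29, adjusted p = 2.3e-08, adjusted p = 0.212 with an estimated correlation). T and NK cell markers had 14 of 30 fallen and 17 when adjusted over the list alone (median -0.18, adjusted p = 6.2e-10, adjusted p = 0.0662 with an estimated correlation). Hsd3b5 (1.52), Cyp7a1 (1.21), Igfbp2 (1.09) and Ces3b (1.07) passed as well, but their calls ended without male hUSF1 replicate 1 (adjusted p = 0.0516, 0.0835, 0.0962 and 0.0765). Those of Hsd3b5, Igfbp2 and Ces3b also ended without male eGFP replicate 2 (0.0587, 0.0896 and 0.0603), that of Cyp7a1 without male eGFP replicate 3 (0.0723) or male hUSF1 replicate 3 (0.0508), and that of Igfbp2 without male hUSF1 replicate 3 (0.0717). The count of 2403 became 1234 without male eGFP replicate 2 and 1400 without male hUSF1 replicate 1.

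**Figure D3:**
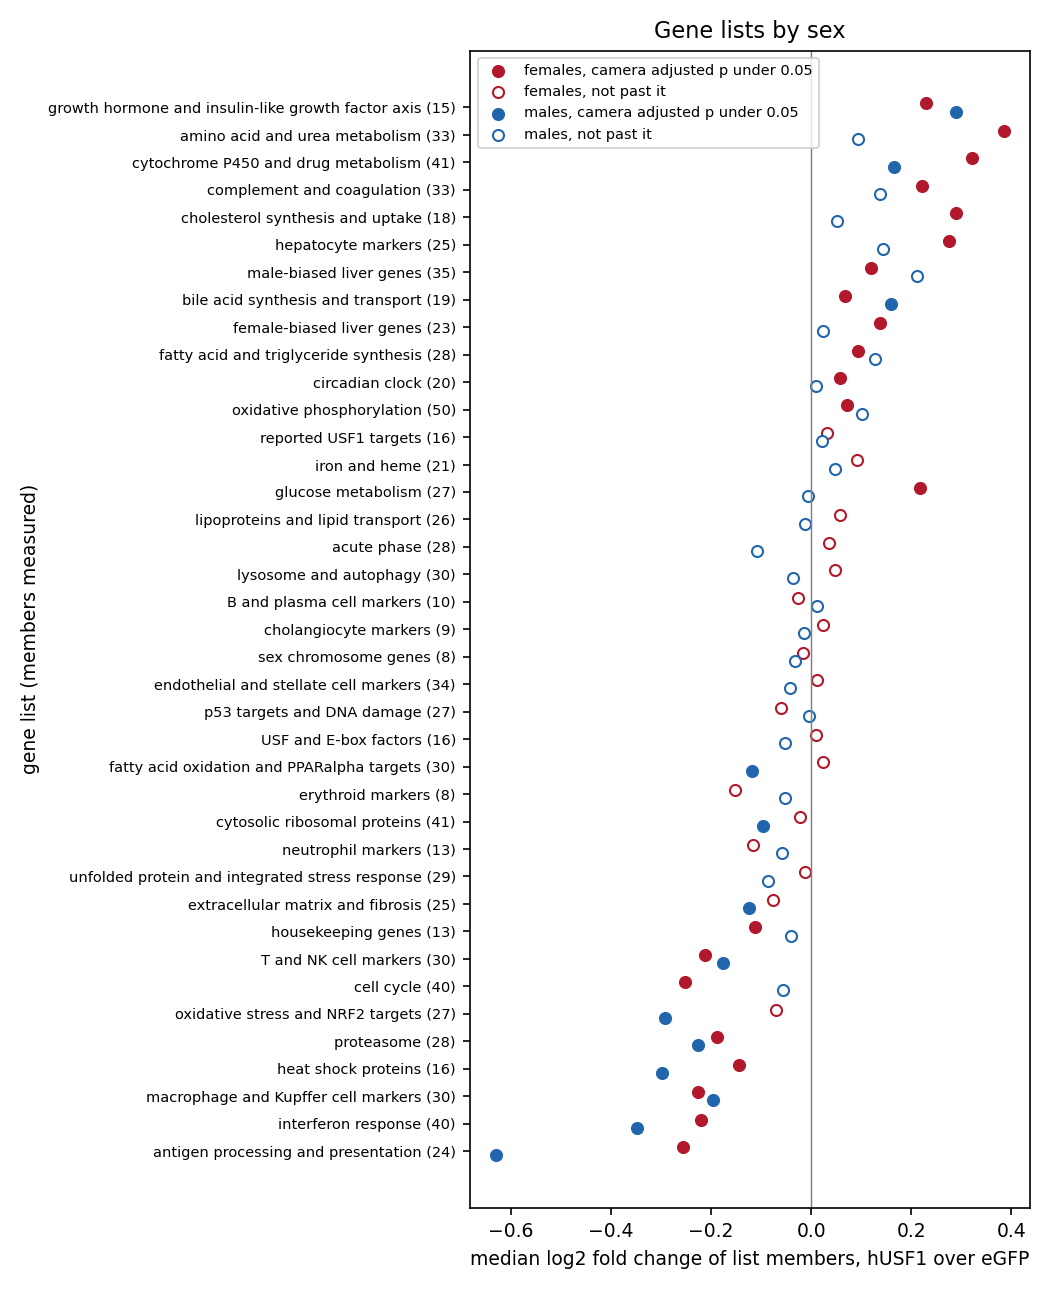
Median log2 fold change of hUSF1 over eGFP for the measured members of each of 39 gene lists, in females (red) and males (blue). Filled points have a camera adjusted p under 0.05 with the preset correlation, of which 3 lists in females and 0 in males held with an estimated correlation. Antigen presentation has the lowest medians, -0.26 in females and -0.63 in males.

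The effects in the sexes were then set against each other. Features that rose in both numbered 168, where independent lists of these sizes would share 43.3, and 188 fell in both, where 50.8 would be shared. Another 83 passed in opposite directions, where 94.5 would be shared. The expected numbers ignore that both comparisons use the same estimate of each feature's spread. A feature with a small spread passes more easily in both sexes, so the expected numbers may be too low. H2-Ab1, H2-Eb1 and Ubd belonged to those that fell in both sexes, and Rgs16 and Hamp2 to those that rose in both. Across genes, which are not independent replicates, the log2 fold changes of females and males had a Pearson r of 0.334 and a Spearman rho of 0.191, and 55.0% had the same sign. At an unadjusted p under 0.05 the number shared in direction was 1225 in place of 356. Of these 617 rose and 608 fell, where 262.5 and 278.8 would be shared. Another 461 went in opposite directions, where 546 would be shared.

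**Figure D4:**
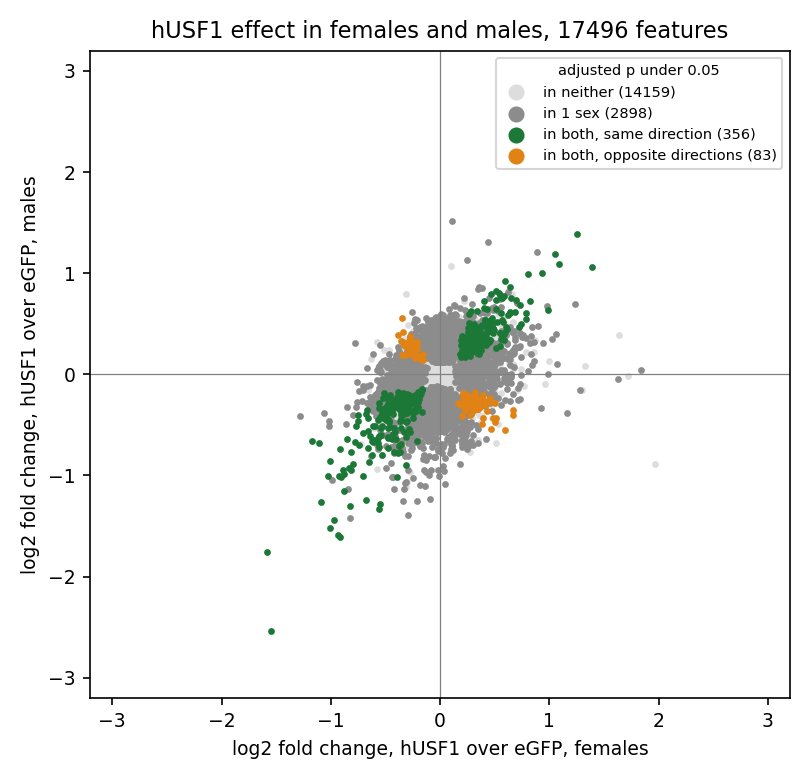
Log2 fold change of hUSF1 over eGFP in females (horizontal axis) and males (vertical axis), 1 point per feature of 17496. Green points (356) passed in both sexes in the same direction, orange points (83) in opposite directions, and 14159 passed in neither sex.

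The interaction, the female effect minus the male effect, tests whether the difference between hUSF1 and eGFP livers was unlike in the sexes. Scd1 rose in females, while its male intensity was 3196 ± 296 (SD, n = 3) with eGFP and 2481 ± 549 with hUSF1 (-0.38, adjusted p = 0.181), and the effects differed by 1.54 (SE 0.25, adjusted p = 0.00846). Cyp2d9, a male-biased P450 gene, had intensities of 1105 ± 62.9 and 1772 ± 77.5 in females and of 4340 ± 476 and 3263 ± 262 in males, a difference of 1.08 (SE 0.12, adjusted p = 0.00329). Psmb9, an immunoproteasome subunit gene, differed by 0.93, having gone from 954 ± 68.4 to 482 ± 21.7 in males and from 812 ± 65.2 to 801 ± 61.7 in females. The proteasome ATPase gene Psmc1 differed by 0.87, the mitochondrial protein gene Chchd10 by 0.69 (SE 0.05, adjusted p = 0.000325), Gstm5, a glutathione transferase gene, by 0.73, Lonp2, the peroxisomal Lon protease gene, by 0.58, Fcf1 and Rrp36, genes of ribosome biogenesis, by 0.79 and 0.49, Naca by 0.73 and Zdhhc4 by 0.50. In limma's test of the difference 1008 features passed, 507 with the higher effect in females and 501 with the lower, and 3700 had an unadjusted p under 0.05.

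Camera called 11 lists for the interaction, 10 with the higher effect in females, among them the antigen presentation list (median 0.33, 5 of 24 genes and 11 when adjusted over the list alone, adjusted p = 0.524 with an estimated correlation). With an estimated correlation and with fry 0 lists passed. The count of 1008 became 663 without female eGFP replicate 2, 660 without female hUSF1 replicate 1, 608 without female hUSF1 replicate 3, 635 without male eGFP replicate 2 and 574 without male hUSF1 replicate 2.

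Females and males were compared under each vector, which also checks the sex labels. Among eGFP livers Xist, the RNA of the inactive X chromosome, was at least 10.1-fold higher in females, where it stood at 578 ± 202 (SD, n = 3) and males read 30.1 ± 0.5, below the arrays' median. The Y-linked genes Eif2s3y and Kdm5d were at least 3.43-fold and 1.12-fold higher in males, and Kdm6a, an X-linked gene that escapes inactivation, was 0.67 log2 units higher in females. Sult2a2, a sulfotransferase gene, had 2123 ± 312 in females and 42.6 ± 3.0 in males (5.02 log2 units, SE 0.08, adjusted p = 6.9e-11). The P450 genes Cyp2b13 and Cyp2b9 were higher in females by 4.64 and 3.24, A1bg by 2.96, Hamp2 by 1.97 and the cyclin D1 gene Ccnd1 by 1.45. Genes lower in females included the fatty acid hydroxylase genes Cyp4a12b (-3.68) and Cyp4a12a (-3.59), the major urinary protein genes Mup5 (-2.78), Mup21 (-2.70), Mup6 (-2.36) and Mup20 (-1.98), the scavenger receptor gene Scara5 (-2.63), the complement gene C6 (-2.54), Cyp2d9 (-1.95) and Nat8, at 34.3 ± 2.5 in females and 207 ± 25.1 in males. Cyp2b23 (1.94), the ectonucleotidase gene Nt5e (1.87) and the cell cycle inhibitor gene Cdkn1c (1.48) were also higher in females.

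In eGFP livers 3618 features differed between the sexes, 1927 higher and 1691 lower in females, 94 of them by more than 1 log2 unit, and 5571 had an unadjusted p under 0.05. Of 35 male-biased liver genes 22 were lower in females and 0 higher, 26 when adjusted over the list alone (median -0.92, adjusted p = 1.3e-16, adjusted p = 0.152 with an estimated correlation). Of 23 female-biased genes 13 were higher and 1 lower, 14 and 1 when adjusted over the list alone (median 0.26, adjusted p = 1.0e-05, adjusted p = 0.259 with an estimated correlation). Cell cycle genes were higher in females for 21 of 40, 24 and 1 lower when adjusted over the list alone (median 0.38, adjusted p = 1.3e-06, adjusted p = 0.485 with an estimated correlation). In hUSF1 livers 1940 features differed, 915 higher and 1025 lower in females, 83 of them by more than 1 log2 unit, and 4630 had an unadjusted p under 0.05. There the female-biased list had 13 of 23 genes higher in females and 13 when adjusted over the list alone (median 0.35, adjusted p = 0.0469 with an estimated correlation), and the male-biased list 22 of 35 lower, 25 lower and 2 higher when adjusted over the list alone (median -0.83, adjusted p = 0.0612 with an estimated correlation). Antigen presentation genes were higher in female hUSF1 livers for 16 of 24 and 20 when adjusted over the list alone (median 0.50, adjusted p = 4.9e-13, adjusted p = 0.0612 with an estimated correlation), and interferon genes for 19 of 40 and 24 when adjusted over the list alone (median 0.33, adjusted p = 6.2e-13, adjusted p = 0.207 with an estimated correlation). Between the sexes with eGFP the interferon list passed too (adjusted p = 0.0361, adjusted p = 0.685 with an estimated correlation), and the antigen presentation list did not. The count of 1940 became 839 without female hUSF1 replicate 1, 1065 without female hUSF1 replicate 3, 890 without male hUSF1 replicate 1 and 1189 without male hUSF1 replicate 2.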

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

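The tests of a single unusual array, of cyclic loess and of splits with the averaged effect taken out were chosen only after the result was seen.

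The hUSF1 effect differed between females and males by the test of the interaction itself for 1008 features. Among named genes with the smallest p the female minus male difference in log2 units was 0.69 for Chchd10, 0.73 for Gstm5, 0.58 for Lonp2, 0.79 for Fcf1, 0.87 for Psmc1, 1.08 for Cyp2d9, 0.49 for Rrp36, 0.73 for Naca, 0.50 for Zdhhc4 and 0.93 for Psmb9, and it was 1.54 for Scd1. For Naca and Rrp36 the other kept probes read between -0.02 and 0.03 in the averaged comparison, and the interaction of those probes is not given here. Camera with the preset correlation also called 11 lists, whose median differences were 0.33 for antigen presentation, 0.26 for amino acid and urea metabolism, 0.26 for oxidative stress and NRF2 targets, 0.24 for cholesterol synthesis and uptake, 0.20 for the acute phase, 0.19 for female-biased genes, 0.15 for the interferon response, 0.12 for complement and coagulation, 0.0919 for cytochrome P450 and drug metabolism, 0.0809 for lysosome and autophagy and -0.23 for the cell cycle. With an estimated correlation 0 of these lists passed (adjusted p between 0.524 and 0.740), and with fry 0 passed.

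Of 100 splits of the arrays within the sexes 2 gave a count of genes as large as 1008, the real one and the split that turns 1 sex round, whose 2626 genes are the averaged effect, and 47 gave 11 lists or more, the highest other 24. These splits decide nothing for the interaction, because most of them put the averaged effect into the spread within groups. With the averaged effect taken out of every feature first, 1 of 100 splits, the real one, gave 1008 genes and the highest other gave 13. A random split of these samples is thus an unlikely source of the gene count. Mixed splits still put the interaction into the spread within groups, which can lower their counts. Differences between animals or in handling are not excluded, because the labels do not say whether samples are separate animals. For the lists 15 of 100 splits then gave 11 lists or more and the highest other gave 16. Many mixed splits keep part of the interaction in their contrast, which can raise their counts. The splits therefore cannot decide for the lists, and a random split stays open. A single unusual array as the whole cause is argued against by the lowest count with 1 array left out, 574 without male hUSF1 replicate 2. A bias with signal intensity that cyclic loess removes, as the source of most calls, is argued against by the count after it, 941, of which 865 were shared with the 1008. Cyclic loess moved the calls from 507 higher and 501 lower to 578 and 363, so such a bias in part of them stays open. Trend and robust options kept 678 of the 1008 calls and the offset of 16 kept 763. A real difference between the sexes in the response, a difference in the dose of virus that reached the liver or in the level of hUSF1, and the order of handling stay open and untested, because no measure of them is in these data.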

How the results depend on the processing

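The normexp offset of 16 was chosen only after the data were seen, and the other settings were planned. Under each setting other than leaving out an array the 6 gene counts stayed within 1.5 times. With camera at an estimated correlation the lists called were 5 for the averaged effect, 3 in females, 0 in males, 0 for the interaction, 0 between the sexes with eGFP and 1 with hUSF1, and with fry 0 for the interaction, and the cause was not tested. At an unadjusted p the overlap of the sexes was 1225 in place of 356. With 1 array left out the counts ran from 556 to 1517 in females, 1234 to 2381 in males, 574 to 863 for the interaction, 839 to 2081 between the sexes with hUSF1, 1821 to 2415 for the averaged effect and 2636 to 3667 between the sexes with eGFP, and from 7 to 14 lists for the interaction. Cyclic loess put 61.4% of the interaction calls on the higher side, 578 against 363, where 50.3% were before, and eBayes with trend and robust options 60.3%. The side with more calls turned elsewhere too. In males it went from 1226 higher and 1177 lower to 1015 and 1302 with cyclic loess, 1217 and 1316 with trend and robust options, 1275 and 1295 for the deposited values, 1245 and 1345 at the offset of 16, 1580 and 1615 over all kept probes and 1067 and 1068 with a replicate block. Between the sexes with eGFP it went from 1927 and 1691 to 1709 and 1784 with cyclic loess and 2356 and 2387 over all kept probes, and with hUSF1 from 915 and 1025 to 969 and 944 with cyclic loess, 1063 and 1036 with trend and robust options and 1131 and 1072 at the offset of 16. For the averaged effect it went from 1303 and 1323 to 1317 and 1296 with the filter on all 12 arrays. It also turned in males without male eGFP replicate 2 (615 and 619) or male hUSF1 replicate 1 (699 and 701), and for the interaction without male eGFP replicate 1 (384 and 395) or 3 (420 and 436). Of the list calls, that of cytochrome P450 genes in males was lost without a filter (adjusted p = 0.0577), that of glucose metabolism between the sexes with eGFP with a replicate block (0.0570), and those of glucose metabolism and neutrophil markers in the averaged effect with cyclic loess (0.0511 for both). For the genes named, 3233 of 3315 values under other settings kept direction and side of the threshold, 74 lost the call, 6 gained it and 2 reversed. The reversed value was that of Usf1, which never passed and ran from -0.00598 to 0.0460 with 1 array left out. The gained call was that of Usf2 on the probe used, 0.22 with adjusted p = 0.0413 for the deposited values and 0.27 with adjusted p = 0.0363 at the offset of 16. Over its settings the adjusted p ranged from 0.0352 to 0.114. Its other kept probe fell in males. Other than by leaving out an array, 15 calls were lost, among them those of Hsd3b5 in the averaged effect and of Igfbp2 and Sult2a8 in females without a filter or with trend and robust options, and those of Hamp2 and Slc4a1 in females and of Hsd3b5, Igfbp2 and Ces3b in males with the compared arrays alone, and the cause was not tested. The labels do not say whether replicate numbers pair the arrays. Residuals of arrays with the same number correlated from -0.283 to 0.207, with 2 of 18 pairs over 0.1. Those with other numbers in different groups correlated from -0.299 to 0.26, with 8 of 36 over 0.1. Residuals sum to 0 within each group of 3, so these values do not decide the question. With a replicate block 672 of the 1008 interaction calls were kept. A replicate block gave 1215, 2135, 2361, 742, 3388 and 1690 genes (females, males, averaged, interaction, sexes with eGFP, sexes with hUSF1) and 24, 21, 14, 11, 13 and 16 lists (averaged, females, males, interaction, sexes with eGFP, sexes with hUSF1), and ended the call of Apoe among the genes named. Not run were median scaling, which moves nothing because the columns share 1 distribution, a slide block, since the files give no slide, and normexp in place of neqc, which is the setting used. Signal close to the lowest intensity, 25.2, limits what can be said of dim genes.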

Other observations

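The tests of dilution by hepatocytes, of leukocyte number and of splits with the interaction taken out were chosen only after the result was seen.

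Some lists without a call in the averaged comparison held genes that passed and that moved in opposite directions. Of 27 p53 and DNA damage genes 3 rose and 4 fell, with the same counts when adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, fell by 0.55 (SE 0.11, adjusted p = 0.00836), and its other 2 probes read -0.55 and -0.47. Mdm2, which encodes the ubiquitin ligase of p53, fell by 0.31 and its other probe read -0.28. Sesn1 rose by 0.23, although its other probes read 0.00 and 0.01, and Dcxr, a xylulose reductase gene, rose by 0.47 (SE 0.07, adjusted p = 0.00185). Of 20 circadian clock genes 4 rose and 1 fell, with the same counts when adjusted over the list alone, among them Per3 (0.28) and Tef (0.48), each with another probe under 0.07, and the kinase gene Csnk1d (-0.20), whose other 4 probes read between -0.15 and 0.05. All of these lay on 1 side of the eGFP means in 6 of 6 hUSF1 arrays.

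In the extracellular matrix list 7 of 25 genes fell and 3 rose, 9 and 3 when adjusted over the list alone (adjusted p = 0.0198, adjusted p = 0.485 with an estimated correlation). That call also ended without female eGFP replicate 2 (adjusted p = 0.0834), female hUSF1 replicate 1 (0.0529), male eGFP replicate 2 (0.0843) or male hUSF1 replicate 1 (0.0794). Vim, an intermediate filament gene of mesenchymal cells and leukocytes, fell by 0.60 (SE 0.09, adjusted p = 0.00211), and Tgfb1, a profibrotic cytokine gene, by 0.22 (SE 0.04). Mmp13, a collagenase gene, fell by 0.53 on the probe used, and its other probes read -0.06 and 0.03. Of 13 housekeeping genes 3 fell and 0 rose, 6 when adjusted over the list alone. Actb, the β-actin gene often used as a reference, fell by 0.48 (SE 0.11, adjusted p = 0.0127) in 6 of 6 hUSF1 arrays, but its other probes read 0.31 and -0.40, and Ywhaz fell by 0.39, with its other probe at -0.12.

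The lower antigen presentation, T and NK cell and interferon genes of hUSF1 livers may have technical or biological sources. A bias with signal intensity is argued against, since 0% of 10000 random lists matched on mean signal had a median as low as that of each of the 3 lists. Dilution of every other cell type by more hepatocyte RNA is argued against by markers over an intensity of 100. There the median of 16 endothelial and stellate markers (-0.01) lay 0.59 above that of 9 T and NK cell markers (-0.60, two-sided exact permutation p = 0.0012). Over all 34 and 30 members it lay 0.13 above (-0.02 against -0.15, permutation p = 0.00061). The random lists and the permutations treat genes as independent, though genes of a list vary together across the same arrays. Their shares and p-values therefore do not measure the spread between livers, and the medians describe these arrays only. Fewer leukocytes with no change of interferon response in other cells stays open, because leukocytes also express the 40 interferon genes, whose median was -0.32. As a hypothesis the pattern could reflect fewer or less active leukocytes, a weaker response to the virus or a difference in virus dose between the vectors, and the last of these has no measure here. Without a group that received no virus, lower values with hUSF1 cannot be told apart from higher values with eGFP.

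A further hypothesis was that within a group the arrays with lower immune scores have higher P450 and amino acid scores. The deviations from the group means over 12 arrays had a Pearson r of 0.0323 (p = 0.913 over 1296 permutations within groups) and a Spearman rho of 0.133 (permutation p = 0.693). Without the 2 arrays farthest from the median r was 0.182. The finding is negative, with 1 relation computed, so no adjustment was made.

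Other splits of the arrays were fitted for each comparison. For the hUSF1 comparisons they were meant to stand for no effect of the vector, and for the sex comparisons for no difference between the sexes. Mixed splits do so only in part. They put arrays of both real groups on each side in unequal numbers, so many of them keep part of the real effect. For the averaged effect some splits also keep the real labels of 1 sex. For the averaged effect 1 of 100 splits, the real one, gave 2626 genes, and the highest other gave 1008, which is the interaction. With the interaction taken out of every feature first, 1 of 100 gave 2626 and the highest other gave 1. A random split of these samples is thus an unlikely source of the gene count. Mixed splits put the averaged effect into the spread within groups, which can lower their counts. Many also keep part of it in the contrast, which can raise them. For its lists 2 of 100 splits gave 24, the real one and the highest other, so the share was under 0.05, but the number of lists alone does not set the real split apart. With the interaction taken out 1 of 100 gave 24 and the highest other gave 23. Because many splits keep part of the effect, these other counts of lists are not a level for no effect. For the overlap of the sexes 1 of 100 splits, the real one, gave 356, and the highest other gave 83. That other split turns 1 sex round, and its 83 are the features that passed in opposite directions. Mixed splits within 1 sex called at most 1 gene in females and 0 in males, so they could share almost none. The splits therefore do not test whether the sexes agree. Splits do not exclude differences between animals or in handling. The 100 splits were drawn from 200. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. There the real and highest other gene counts were 1373 and 1 in females, 2403 and 0 in males, 3618 and 0 between the sexes with eGFP, and 1940 and 0 between the sexes with hUSF1. The real and highest other list counts were 21 and 15 in females, 13 and 18 in males, where 4 of 10 splits gave at least 13, 14 and 18 between the sexes with eGFP, where 2 of 10 gave at least 14, and 16 and 13 between the sexes with hUSF1.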
